A study of Hordeum vulgare with 18 samples.

How the data were processed

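Gene expression was measured in shoots and roots of germinated barley (Hordeum vulgare, cultivar Haruna Nijo) on 18 custom Agilent arrays with 2 colours and 60-base probes. Per the labels' protocols, seeds germinated for 4 days at 24 °C, 3 seedlings per sample were moved to dishes holding 4.5 mL of 10 mM AlCl3, and shoots and roots were harvested separately. On every array the Cy5 channel held RNA of a treated tissue (3, 6 or 24 h) and the Cy3 channel held RNA of the same untreated tissue at 0 h. The dye orientation was the same on all 18 arrays, so a dye effect of a probe cannot be separated from the treatment in a ratio against 0 h. In a difference between 2 groups of arrays it cancels only where it is the same in both groups. The labels used here name no untreated sample at 3, 6 or 24 h, so the ratios hold the effects of aluminum, of the transfer and of the time of day together.

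The deposited scanner files give the intensity of each spot and its local background in both channels, extracted by the authors with Agilent Feature Extraction. The submitters' processing notes give version 9.1, and the file headers give 9.5.3.1 for 16 arrays and 9.1.3.1 for 2 arrays, the 6 h arrays of replicate 1. The files also hold the authors' log10 ratio of Cy5 over Cy3, per the file headers after Agilent's own background subtraction and dye normalization. The deposited series table held these same log10 ratios: the largest difference over 18 columns was 0. Its column medians lay between -0.0183 and 0.00900, and its scale, centring and direction were thereby settled.

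The intensities were read with limma 3.58.1 in R 4.3.3. Mean spot signals were corrected against the median local background with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0. Flagged spots were left out, saturated spots were kept. Of 42483 probes, the 39384 that stood well above background in at least 1 channel on at least 4 of the 16 arrays at 3 and 6 h were tested. Median background-subtracted signals ran from 600.3 to 1346 units in Cy3 and from 928.4 to 3358 in Cy5, and between 85.8% and 92.2% of probes stood well above background per array and channel. The number of arrays limits the precision.

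Arrays were grouped by tissue and time from their titles: shoot 3 h, shoot 6 h, root 3 h and root 6 h with 4 biological replicates each, and shoot 24 h and root 24 h with 1 array each. The labels do not say whether replicates were grown on separate days. Group means were fitted to the 16 arrays with limma's lmFit and eBayes, and each mean log2 ratio was tested against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same fit gave 6 h minus 3 h within each tissue and root minus shoot at each time. Each probe had 1 estimate of spread shared by all 4 groups. It understates the spread of a group that varies more than the others, where p-values can be too low, and overstates that of a group that varies less. Untreated root and shoot were compared on the Cy3 channel after loess and Aquantile normalization, with 1 value per tissue and replicate (mean of its 3 h and 6 h arrays), 4 against 4. The 24 h arrays gave values without a test. All adjusted p-values below are limma's.

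The replicate numbers come from the labels. Deviations from the group means of same-numbered arrays correlated at 0.18 to 0.82 in all 16 pairs checked, so same-numbered arrays resembled each other. Pairs with different numbers were not checked. For replicates 2, 3 and 4 the number is also the slide, so a pairing of the samples cannot be told from a shared slide. A fit with the replicate number as a block is given where it moved a count by over 1.5 times. For a ratio against 0 h that block treats the 4 replicates as fixed, so its p-values do not speak for other replicates. The Cy3 signals of the 3 h and 6 h arrays of the same tissue and replicate differed by a median absolute log2 of 0.034 to 0.114, against 0.134 to 0.348 between replicates. In replicate 1, with 3 h and 6 h on separate slides, it was 0.114 in shoots and 0.105 in roots. The ratios at 3 and 6 h are therefore taken to share 0 h samples, though in replicates 2, 3 and 4 a shared slide could add to the likeness.

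The arrays lay on 6 slides scanned in 3 periods, a period being the calendar year of the scan in the file headers. The 24 h arrays, both of replicate 1, had a slide and a period of their own. Replicates 2, 3 and 4 each had a slide of their own with all 4 groups and were scanned in the same period. The 3 h and 6 h arrays of replicate 1 lay on a slide each and were scanned in another period. Removing replicate 1 leaves arrays of a single scan period. Of the probes called against 0 h, at least 97.2% had the sign of the group mean within each replicate, and so on each slide of replicates 2, 3 and 4, except for replicate 1 of shoot 6 h with 93.1%. The calls were made on these same arrays, which all but fixes the signs, so the shares do not test the calls within a slide.

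The probes carry clone names. None of the probe or clone names (0) occurred in the reference gene table supplied (assembly MorexV3), and 0 of 24 gene lists (transport, organic acids, detoxification, cell wall, hormones, marker genes and others) matched a probe, so no list was tested and no gene is named. The rule for named probes was fixed before the data were examined: probes past adjusted p 0.05 that moved the same way in all 4 replicates, 1 per clone, by largest change. Its condition on a product name had to be dropped, and at most 2 rising and 2 falling probes are named per comparison, by probe name and sequence. Agreement of the 4 replicates, given below with the named probes, was a condition of their choice and is no separate support.

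The fit was tested on simulated data, 38380 probes with 200 of them changed. For shoot at 3 h against 0 h it recovered 37.3% of probes changed by 0.50 log2 units, 86.6% at 1 and 93.9% at 2, with 7 false calls among 152. For root minus shoot at 3 h it recovered 23.9%, 67.2% and 87.9%, with 4 false calls among 123. The simulated noise was drawn independently for each probe and array and so lacked the likeness of same-numbered arrays. These false calls therefore do not speak for the share of false calls in the real data. Alternatives covered background correction, offset, normalization, the filter on dim probes, flagged spots, the variance prior, the arrays in the fit, replicate and slide as blocks, a fold threshold and leaving out each replicate. Figures were drawn with Python 3.11.15.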

Results

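The time course followed seedlings moved to 10 mM AlCl3, a form of soluble aluminum that is toxic to roots in acid soils, and asked how transcript levels in shoots and roots changed after 3, 6 and 24 h relative to untreated tissue at 0 h. There were 4 arrays for each tissue at 3 and at 6 h and 1 array for each tissue at 24 h. Changes are log2 ratios of treated over 0 h tissue, given as mean ± SD with n = 4.

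In shoots at 3 h, transcripts at 3686 of 39384 probes were higher and at 3413 lower than at 0 h (adjusted p under 0.05, limma). Most changes were small, with a median size of 0.46. At least 2-fold changes were mainly rises, 479 against 158 falls. The largest rises were at Hv1054H21_1 (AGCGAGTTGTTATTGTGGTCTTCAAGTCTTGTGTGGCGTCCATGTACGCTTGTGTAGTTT), at 5.42 ± 1.93 (adjusted p = 0.014), and Hv2083E12_1 (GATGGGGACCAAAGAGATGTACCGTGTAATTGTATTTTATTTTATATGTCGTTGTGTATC), at 5.21 ± 2.15 (adjusted p = 0.027). The largest falls were at Hv3085E19_1 (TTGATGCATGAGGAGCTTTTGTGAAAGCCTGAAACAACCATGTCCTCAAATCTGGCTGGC), at -3.36 ± 1.51 (adjusted p = 0.00093), and Hv2104L08_1 (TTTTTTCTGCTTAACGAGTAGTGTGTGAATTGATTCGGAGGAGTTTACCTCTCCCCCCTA), at -2.39 ± 1.34 (adjusted p = 0.0025). Each of these 4 probes moved the same way in 4 of 4 replicates, which the rule for named probes required. Hv2083E12_1 shares at least 18 bases with Hv1044M10_1, which rose by 4.72, so the pair may report related transcripts and is not independent. Both rises were larger in replicates 1 and 4 (8.07 and 5.62 for Hv1054H21_1) than in replicates 2 and 3 (3.83 and 4.15). Hv1054H21_1 missed the threshold without replicate 1 or 3 (adjusted p = 0.08 and 0.054), and Hv2083E12_1 without replicate 1, 3 or 4 (0.13, 0.07 and 0.076). With the replicate number as a block 11576 probes were called, and without replicate 2, 3 or 4 the count was 4232, 3132 or 3182. Median centring in place of loess gave 12408.

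In shoots at 6 h, 2529 probes were higher and 2287 lower than at 0 h, with 276 rises and 84 falls of at least 2-fold. The same pair of probes rose most, Hv2083E12_1 by 6.10 ± 2.12 (adjusted p = 0.017) and Hv1054H21_1 by 6.08 ± 1.79 (adjusted p = 0.01). The named falls were Hv3140K06_1 (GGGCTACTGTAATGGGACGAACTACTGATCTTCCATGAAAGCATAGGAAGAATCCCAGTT) at -2.38 ± 1.04 (adjusted p = 0.037) and Hv3085E19_1 at -1.90 ± 1.10 (adjusted p = 0.029). All 4 moved the same way in 4 of 4 replicates, as the rule required. Each missed the threshold when the fit held the shoot 6 h arrays alone (adjusted p = 0.057, 0.052, 0.064 and 0.092 in that order). Each also missed it with some replicate left out: Hv2083E12_1 without 1, 3 or 4 (0.055, 0.059 and 0.089), Hv1054H21_1 without 3 (0.053), Hv3140K06_1 without 1, 3 or 4 (0.11, 0.15 and 0.13) and Hv3085E19_1 without 1, 2 or 4 (0.051, 0.11 and 0.25). The fit to the group's own arrays called 152 probes, and the fit with the replicate block called 8935. Median centring gave 10883. The array of replicate 1 correlated at -0.09, -0.02 and 0.32 with those of replicates 2, 3 and 4 of its group. Without it 6925 probes were called, 3052 higher and 3873 lower, so that the balance turned to falls. From replicates 2 to 4 alone, 307 rises and 362 falls of at least 2-fold were called among the 37224 probes measured on the shoot 24 h array. Leaving out replicate 2, 3 or 4 in all groups left 1674, 1744 or 1244.

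In roots at 3 h, 4672 probes were higher and 4233 lower, with 784 rises and 661 falls of at least 2-fold. Hv2011N24_2 (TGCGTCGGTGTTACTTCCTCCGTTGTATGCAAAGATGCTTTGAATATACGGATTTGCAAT) rose by 5.10 ± 0.38 (34.2-fold, adjusted p = 1.1e-08) and Hv2078F04_1 (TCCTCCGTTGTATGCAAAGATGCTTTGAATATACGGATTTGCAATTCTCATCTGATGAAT) by 4.81 ± 0.29 (28.1-fold, adjusted p = 4e-08), each in 4 of 4 replicates. They share at least 18 bases with each other and with Hv2011N24_1 and Hv1125H15_1, so these 4 probes may report the same or closely related transcripts. The largest falls varied more between replicates. Hv2023E18_1 (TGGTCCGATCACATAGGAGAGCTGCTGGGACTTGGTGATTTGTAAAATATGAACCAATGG) fell at -3.55 ± 2.77 (adjusted p = 0.0099), with -5.81 and -5.93 in replicates 2 and 3 and -2.10 and -0.37 in replicates 1 and 4. Hv2127O24_2 (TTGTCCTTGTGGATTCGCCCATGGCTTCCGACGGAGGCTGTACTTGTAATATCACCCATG) fell at -3.17 ± 2.40 (adjusted p = 0.01). Before treatment both falling probes were lower in roots than in shoots (log2 difference -4.10 and -5.53), as were both named rises (-6.27 and -6.18). Without replicate 2 both falls missed the threshold (adjusted p = 0.096 and 0.1), and without replicate 3 as well (0.077 and 0.07). The SD of Hv2023E18_1 was 0.28 and 0.22 in shoots at 3 and 6 h, so the shared estimate understates its spread in root 3 h. With the root 3 h arrays alone 1748 probes were called and both falls missed the threshold (adjusted p = 0.12 and 0.11). Without replicate 2, 3 or 4 the counts were 5175, 5571 and 5722.

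In roots at 6 h, 2272 probes were higher and 1730 lower than at 0 h, with 431 rises and 195 falls of at least 2-fold. Hv2056I16_1 (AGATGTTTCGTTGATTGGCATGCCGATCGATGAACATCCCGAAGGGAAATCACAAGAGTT) rose by 3.68 ± 1.41 (adjusted p = 0.00015) and Hv1068G14_1 (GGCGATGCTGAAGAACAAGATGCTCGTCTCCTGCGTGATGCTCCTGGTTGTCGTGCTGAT) by 3.56 ± 0.37 (11.8-fold, adjusted p = 1.4e-07), each in 4 of 4 replicates. Agilent's own log ratios put Hv2056I16_1 at 5.69 (adjusted p = 1.1e-05). At 3 h Hv1068G14_1 stood at 3.61 ± 0.28. The named falls were Hv2022I18_1 (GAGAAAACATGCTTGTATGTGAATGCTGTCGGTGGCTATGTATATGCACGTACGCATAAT) at -2.56 ± 1.98 (adjusted p = 0.046) and Hv1147O10_1 (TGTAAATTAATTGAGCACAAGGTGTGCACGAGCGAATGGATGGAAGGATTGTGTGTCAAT) at -2.40 ± 1.90 (adjusted p = 0.036). Before treatment both were lower in roots than in shoots (log2 difference -3.84 and -4.40), as were both named rises (-1.54 and -2.38). Both falls were largest in replicates 2 and 3 and missed the threshold without replicate 1, 2 or 3 (adjusted p = 0.1, 0.21 and 0.21 for Hv2022I18_1, and 0.066, 0.18 and 0.21 for Hv1147O10_1). Hv2022I18_1 also missed it with an offset of 10 (0.051) and with the slide as a random block (0.059). In shoots at 3 and 6 h the SD was 0.26 and 0.46 for Hv2022I18_1 and 0.24 and 0.29 for Hv1147O10_1. The shared estimate thus understates their spread in root 6 h. With the root 6 h arrays alone Hv2056I16_1 (adjusted p = 0.094) and both falls (0.19 each) missed it and 32 probes were called, with the replicate block 8587, and with median centring 11781. Scale normalization gave 6277. The counts without replicate 2, 3 or 4 were 2151, 982 and 1529.

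**Figure D1:**
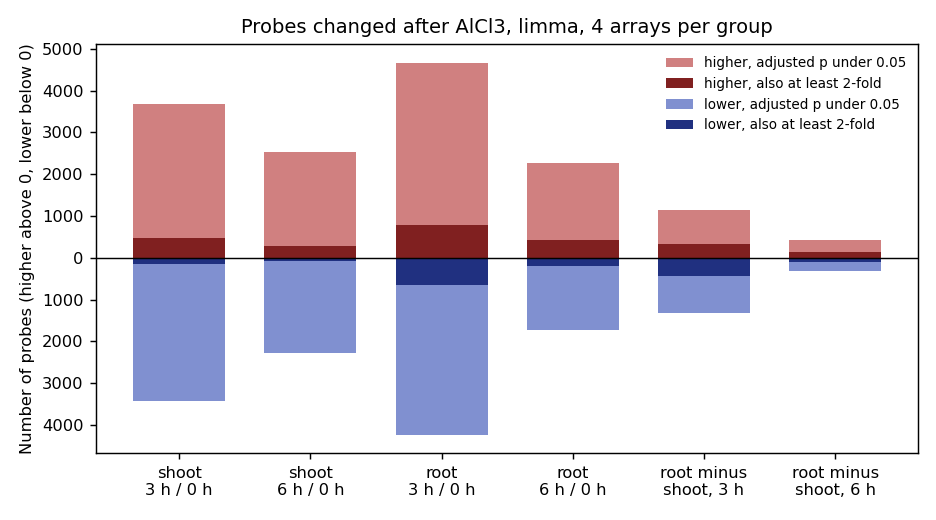
Number of probes called by limma in each comparison (vertical axis, higher above 0 and lower below 0) for 4 arrays per group, with the part that changed at least 2-fold in dark colour. Roots at 3 h had 4672 higher and 4233 lower probes.

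**Figure D2:**
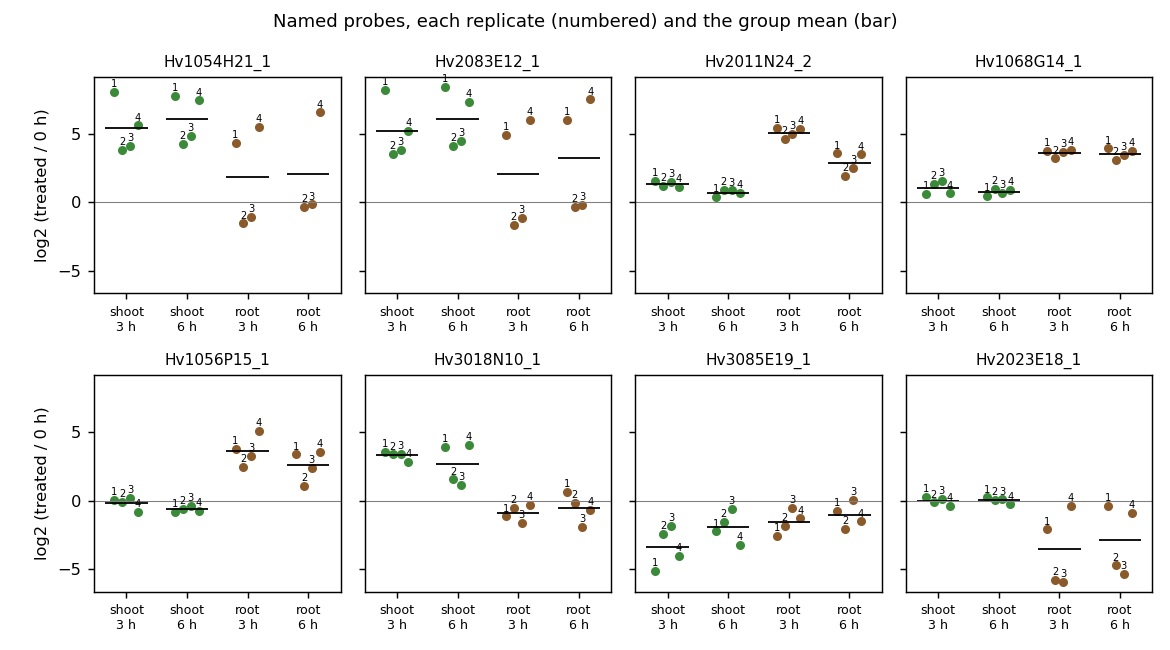
Log2 ratio of treated over 0 h tissue (vertical axis) of 8 named probes in each replicate (numbered points, green for shoot and brown for root), with the group mean as a bar. In root at 3 h Hv2011N24_2 (SD 0.38) and Hv1068G14_1 (SD 0.28) lay close together in the 4 replicates, while Hv1054H21_1 in root at 3 h ran from -1.53 to 5.52.

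Between 3 and 6 h no probe changed past the threshold in either tissue. In shoots limma called 0 probes, with 892 at an unadjusted p under 0.05, and in roots 0, with 3837. Among the smallest p-values in roots, Hv2083H15_1 differed by 1.39, Hv2051P04_1 by -0.60 and Hv1125H15_1 by -1.85, from 4.66 at 3 h to 2.81 at 6 h (adjusted p = 0.05 after rounding for each, none of them past the threshold). In shoots they belonged to Hv2098K09_1, higher at 6 h by 1.18 (adjusted p = 0.72), and Hv1046O12_1, by 1.30 (adjusted p = 0.91). With the replicate block 12 probes passed in roots and 0 in shoots. Those 12 included Hv2011N24_2, which went from 5.10 at 3 h to 2.89 at 6 h (blocked adjusted p = 0.043), and 8 of the 12 were lower at 6 h. With the slide as a random block the count in roots was 80.

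The direct test of roots against shoots at 3 h found 1141 probes with a higher and 1323 with a lower log2 ratio in roots, of which 333 and 422 differed at least 2-fold. Hv1056P15_1 (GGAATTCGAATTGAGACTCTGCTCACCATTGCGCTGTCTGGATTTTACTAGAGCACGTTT) stood at 3.66 ± 1.10 in roots and -0.16 ± 0.44 in shoots, a difference of 3.82 (adjusted p = 0.0015). Hv2011N24_1 (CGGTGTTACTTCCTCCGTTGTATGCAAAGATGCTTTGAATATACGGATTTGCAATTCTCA) differed by 3.71 (adjusted p = 6e-05), at 4.99 ± 0.35 in roots and 1.28 ± 0.21 in shoots. Hv3018N10_1 (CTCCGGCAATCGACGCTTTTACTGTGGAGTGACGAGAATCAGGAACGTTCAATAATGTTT) went the other way, at -0.90 ± 0.59 in roots and 3.31 ± 0.31 in shoots (difference -4.21, adjusted p = 0.0025), as did Hv1052N20_1 (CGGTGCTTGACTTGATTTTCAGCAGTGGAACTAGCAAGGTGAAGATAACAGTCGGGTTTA) at -1.45 ± 1.07 and 2.50 ± 2.08 (difference -3.95, adjusted p = 0.03). Each of the 4 differences had the same sign in 4 of 4 replicate pairs, as the rule required. Before treatment Hv1056P15_1, Hv2011N24_1 and Hv3018N10_1 were lower in roots than in shoots (log2 difference -2.84, -6.27 and -2.35). Hv1052N20_1 was higher (1.53). A larger rise in roots is thus not a higher level in roots. Hv1052N20_1 missed the threshold with any replicate left out (adjusted p = 0.13, 0.071, 0.1 and 0.079 for replicates 1 to 4) and with the compared arrays alone (0.068). The fit with the replicate block called 6011 probes and that with the slide as a random block 6741. Without replicate 2, 3 or 4 the counts were 876, 788 and 824, and median centring gave 4658.

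At 6 h the tissues differed at 744 probes, 439 with a higher and 305 with a lower ratio in roots. Hv1056P15_1 again differed by 3.24 (adjusted p = 0.0093) and Hv3018N10_1 by -3.21 (adjusted p = 0.024), or by -5.08 with Agilent's own log ratios (adjusted p = 0.036). Hv1119C16_2 (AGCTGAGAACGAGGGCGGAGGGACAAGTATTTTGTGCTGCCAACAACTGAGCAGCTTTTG) stood at 3.42 ± 0.74 in roots and 0.47 ± 0.74 in shoots (difference 2.95, adjusted p = 0.0038). Hv2065F15_1 (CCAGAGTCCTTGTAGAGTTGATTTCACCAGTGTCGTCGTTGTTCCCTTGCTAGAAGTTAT) stood at -2.14 ± 0.59 in roots and 0.10 ± 0.52 in shoots (difference -2.25, adjusted p = 0.0072). The 4 differences had the same sign in 4 of 4 replicate pairs, as the rule required. Before treatment the log2 difference of roots from shoots was -0.84 for Hv1119C16_2 and 2.57 for Hv2065F15_1. Each missed the threshold without replicate 3 (adjusted p = 0.12 for Hv1056P15_1, 0.065 for Hv1119C16_2, 0.097 for Hv3018N10_1 and 0.078 for Hv2065F15_1). Without replicate 4 Hv1056P15_1 (0.058), Hv3018N10_1 (0.22) and Hv2065F15_1 (0.1) missed it, without replicate 2 Hv3018N10_1 (0.096) and Hv2065F15_1 (0.052), and with the compared arrays alone all 4 (0.066, 0.066, 0.15 and 0.066 in the order of the last list). The count depended on the arrays used: 6 probes without replicate 3, 79 without replicate 4, 143 without replicate 2, 1985 without replicate 1, and 2438 when the shoot 6 h array of replicate 1 alone was left out. It was 20 with the compared arrays alone, 2271 with the replicate block and 2893 with the slide as a random block. Median centring gave 894 higher and 1252 lower.

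Many probes were called in both tissues. At 3 h, 2587 probes were called in both tissues, and 2415 of them (93.4%) had changed in the same direction: 1448 rose and 967 fell in both, where independent lists would share 437.3 and 366.8. The other 172 had moved in opposite directions. The difference between tissues was called at all 172, which calls of opposite sign in the same fit all but fix. Among the 2415 with the same direction, the difference was called at 93, at 75 of them with the larger change in roots. At 6 h, 707 probes rose and 391 fell in both tissues, against 145.9 and 100.5 for independent lists, and 50 went opposite ways. In simulations of unchanged groups that kept the likeness of same-numbered arrays (100 draws), a mean of 25.8 probes rose and 41.3 fell in both tissues at 3 h, with maxima of 473 and 1007. At 6 h the means were 17.6 and 23.8, with maxima of 431 and 657. The largest simulated numbers of shared falls therefore exceeded the 967 and 391 observed. Across probes, the mean changes of shoot and root at 3 h correlated at 0.39 (simulated mean 0.37, maximum 0.50) with a covariance of 0.0678 (simulated mean 0.0153). Taken from different replicates in the tissues, the correlation was 0.34 or 0.33. At 6 h the correlation was 0.41 (simulated mean 0.23, maximum 0.40), with a covariance of 0.0504 (simulated mean 0.0114), and 0.37 or 0.31 from different replicates. Median centring gave 3693 shared rises and 1785 shared falls at 3 h, and 3128 and 2094 at 6 h. Probes are not independent replicates.

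Within a tissue, 1788 probes rose and 1701 fell at both 3 and 6 h in shoots (236.7 and 198.2 for independent lists), and 1705 rose and 1198 fell at both times in roots (269.5 and 185.9). The times are taken to share their 0 h samples. Simulated unchanged groups gave maxima of 773 shared rises and 967 shared falls in shoots and of 1304 and 2557 in roots, so the largest simulated number of shared falls in roots exceeded the 1198 observed. The changes at 3 and 6 h correlated across probes at 0.83 in shoots and 0.80 in roots, where unchanged groups gave means of 0.59 and 0.75 and maxima of 0.84 and 0.85, above both observed values. The covariances were 0.103 and 0.137, against simulated means of 0.0206 and 0.0399. With 3 h taken from replicates 1 and 2 and 6 h from replicates 3 and 4, which share no 0 h sample, the correlation was 0.76 in shoots and 0.61 in roots, and with the replicates exchanged 0.51 and 0.61. Each side of this split held 1 of replicates 1 and 4 and 1 of replicates 2 and 3, pairs that resembled each other (below). The split is thus not free of that likeness or of a fixed dye bias.

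To follow the response on arrays that played no part in choosing its probes, probes that changed at least 2-fold in the mean of 3 and 6 h were chosen in 3 replicates and averaged on the replicate left out. Probes that rose in roots averaged 1.42 ± 0.58 at 3 h and 1.04 ± 0.52 at 6 h in roots, and 0.59 ± 0.15 and 0.48 ± 0.15 in shoots. Probes that rose in shoots averaged 1.19 ± 0.44 and 0.98 ± 0.38 in shoots, and 0.79 ± 0.39 and 0.55 ± 0.31 in roots. Probes that fell in roots averaged -1.17 ± 0.76 and -0.88 ± 0.64 in roots but -0.07 ± 0.10 and -0.08 ± 0.11 in shoots, and the last pair turned to 0.08 and 0.04 with median centring. Probes that fell in shoots averaged -0.80 ± 0.31 at 3 h and -0.24 ± 1.09 at 6 h in shoots, where replicate 1 stood at 1.36 and the others at -1.09 to -0.62, and -0.40 ± 0.13 and -0.29 ± 0.08 in roots, below 0 in 4 of 4 replicates. With median centring the shoot 6 h average was -0.06. With 4 replicates an exact two-sided sign-flip test cannot give a p below 0.125, the value of each rising score.

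At 24 h there was 1 array per tissue, on a slide and in a scan period apart from the other times, and no test. In shoots 1015 probes stood at least 2-fold above and 305 below 0 h, and in roots 481 above and 1953 below. The highest shoot ratios were again Hv2083E12_1 at 5.96 and Hv1054H21_1 at 5.58. In roots the highest was Hv2067F22_1 (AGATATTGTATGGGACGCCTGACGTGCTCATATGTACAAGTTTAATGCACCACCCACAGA) at 4.12, which had stood at -0.01 at 3 h and 0.20 at 6 h, and the lowest was Hv3089P10_1 (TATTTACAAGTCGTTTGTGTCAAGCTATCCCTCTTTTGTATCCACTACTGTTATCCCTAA) at -7.00. Of 284 probes called as at least 2-fold rises at 3 h in shoots from replicates 2 to 4, 251 (88.4%) were above 0 on the shoot 24 h array, with a median of 0.58. Of 684 such probes in roots, 332 (48.5%) were above 0 on the root 24 h array, with a median of -0.03, while on the root 3 h array of the same replicate they had a median of 1.37. Of 589 probes called as falls at 3 h in roots, 488 (82.9%) were below 0 at 24 h, with a median of -0.97. Of 134 probes called as falls at 3 h in shoots, 64 (47.8%) were below 0 at 24 h, with a median of 0.12. For probes called at 6 h in the same way, 282 of 307 shoot rises (91.9%, median 0.88) and 160 of 363 root rises (44.1%, median -0.10) were above 0 at 24 h, and 215 of 362 shoot falls (59.4%, median -0.20) and 134 of 171 root falls (78.4%, median -0.89) were below 0. On the 6 h arrays of the same replicate these 4 sets had medians of 0.90, 1.22, 0.85 and -0.52 in that order. The shoot falls had thus not fallen at 6 h in the replicate of the 24 h array. Of all probes, 52.8% in shoots and 48.9% in roots were above 0 at 24 h. Agilent's own log ratios gave 1992 probes in shoots in place of 1320.

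**Figure D3:**
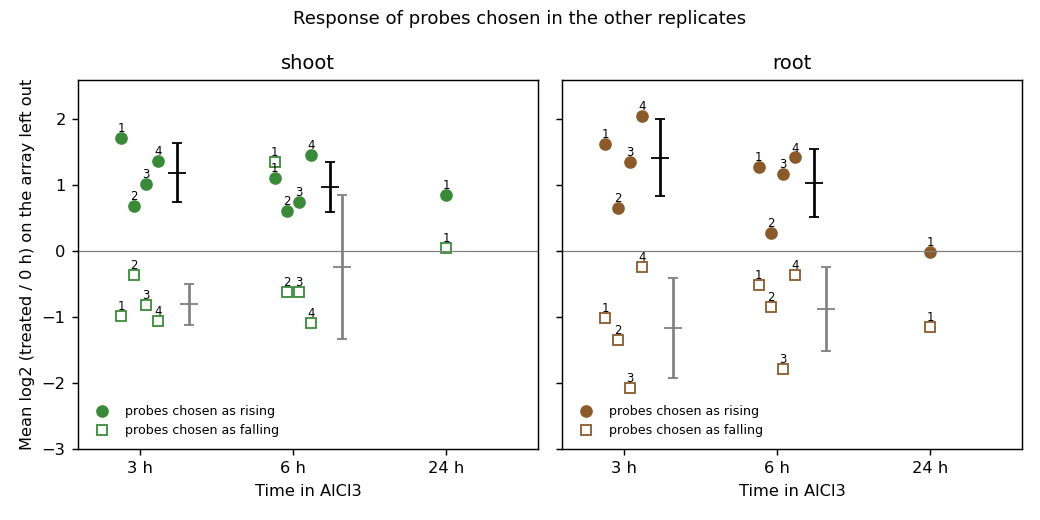
Mean log2 ratio of treated over 0 h tissue (vertical axis) against time in AlCl3 for probes chosen as rising (filled) or falling (open) in the other replicates, shown on the array left out (points numbered by replicate), with mean and SD beside them at 3 and 6 h (black for rising, grey for falling probes). At 24 h the rising probes stood at 0.85 in shoots and -0.01 in roots, and the falling probes at 0.05 and -1.15.

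Before treatment a difference between the tissues was called at most probes. Untreated roots were higher at 18505 and lower at 10039 of 39384 probes (limma, 4 against 4), 8318 and 7078 of them at least 2-fold. The median over all probes was 0.34 above 0. Each difference was tested against 0, so this shift raises the number called higher and lowers the number called lower. The counts and single differences should be read relative to it. The median was 0.329 with quantile normalization of the Cy3 channel alone. Hv2052J12_1 (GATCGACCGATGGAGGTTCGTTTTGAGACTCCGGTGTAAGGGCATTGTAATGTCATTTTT) was higher in roots by 9.94 (adjusted p = 5.6e-09) and stood above background on 2 of 8 shoot arrays. Hv2022H16_1 (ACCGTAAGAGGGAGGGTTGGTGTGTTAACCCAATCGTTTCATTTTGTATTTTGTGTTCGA) was not well above background on any of the 8 shoot arrays and was at least 841.4-fold higher in roots (adjusted p = 1e-08), a bound from the dimmest probe above background on each array. Hv2091G11_1 (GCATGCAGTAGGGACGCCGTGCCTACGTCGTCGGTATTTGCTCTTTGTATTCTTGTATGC) was lower in roots by -9.98 (adjusted p = 7.8e-09), and stood above background on 6 of 8 root arrays, and Hv2031M03_2 (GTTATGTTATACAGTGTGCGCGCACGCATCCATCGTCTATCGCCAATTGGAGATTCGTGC) by -9.75 (adjusted p = 7.3e-10), but stood above background on 2 of 8 root arrays. Both were lower in 4 of 4 replicate pairs, as the rule required. For Hv2052J12_1, Hv2091G11_1 and Hv2031M03_2 the size rests in part on signals not well above background, to which the offset of 50 was added, and is not exact.

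**Figure D4:**
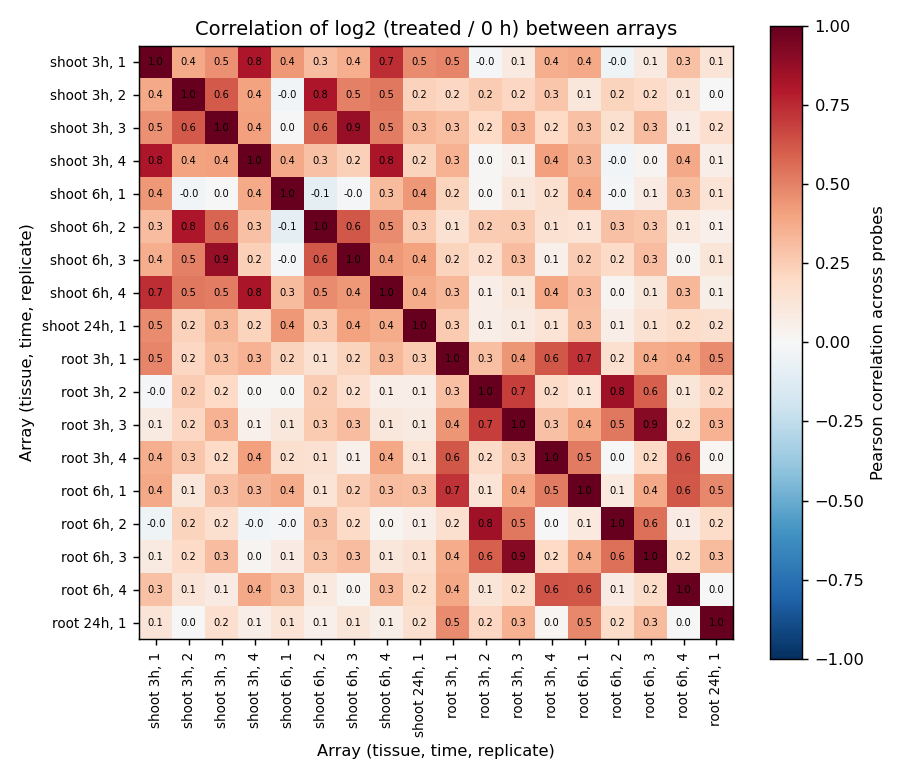
Pearson correlation across probes of the log2 ratios of each pair of the 18 arrays (both axes: tissue, time and replicate), from -1 in blue to 1 in red. The shoot 6 h array of replicate 1 correlated at -0.09 with that of replicate 2, and the 3 h shoot arrays of replicates 1 and 4 at 0.81.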

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

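The tests of a hybridisation fault, of the 0 h samples and of the scan period were chosen after the result was seen. Of 32 groups of 4 values checked with Dixon's test for a sample far from the others, 0 passed the critical value for 4 samples. The results below were picked out because limma's test of the difference between tissues passed. At 3 h the log2 ratio was higher in roots than in shoots by 3.82 for Hv1056P15_1 and by 3.71 for Hv2011N24_1, and differed by -4.21 for Hv3018N10_1 and by -3.95 for Hv1052N20_1. At 6 h the difference was 3.24 for Hv1056P15_1, 2.95 for Hv1119C16_2, -3.21 for Hv3018N10_1 and -2.25 for Hv2065F15_1. A dye effect that is equal on every array cancels in these differences.

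The shoot 6 h array of replicate 1 correlated at -0.09, -0.02 and 0.32 with the other arrays of its group. Root RNA in place of shoot RNA is argued against: over 7304 probes that differed between the untreated tissues, its Cy5 signals had a median position of 0.025 on a scale from 0 (the other shoot 6 h arrays) to 1 (root). A fault of the hybridisation in both channels is argued against as well, since its Cy3 signals differed from those of the shoot 3 h array of replicate 1 by a median of 0.114, below the lowest value of 0.173 between replicates. The 6 h arrays of replicate 1 shared a slide and were extracted with version 9.1.3.1, with 570 flagged spots in shoot and 582 in root. No other array had more than 15. The root array correlated at 0.10, 0.38 and 0.62 with replicates 2, 3 and 4 of its group. A cause in the slide or extraction was not tested. A fault of the Cy5 labelling, a sample from another time or treatment and a real difference of these seedlings stay open. The design offers no biological explanation to test.

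More probes changed the same way in shoots and roots than independent lists would share. For shared changes of at least 2-fold, a fixed dye bias of each probe is argued against as the whole account. In probes chosen in the other replicates the lowest array mean over the highest was -0.01, but the lowest was the single root 24 h array. The 24 h arrays had the same dye orientation but a slide and a scan period of their own. They stood at 0.64 in shoots and -0.02 in roots, against 1.51 and 1.74 on the 3 h arrays of that replicate. Without 24 h, array means ran from 0.78 to 1.74, 0.73 to 1.33, 0.97 to 2.02 and 1.41 to 2.41 within replicates 1 to 4, each with its own set of probes. For shared changes under 2-fold the ratio was 0.22, also below the bound of 0.5 set before the test. It set root 24 h (0.13) against shoot 6 h of replicate 4 (0.59), which had another set of probes, so it rests on 1 array and does not decide. Without 24 h, array means ran from 0.22 to 0.49, 0.26 to 0.40, 0.40 to 0.50 and 0.32 to 0.59 within replicates 1 to 4. Shoot 24 h kept 0.26 of the 0.49 seen at 3 h and every array mean lay above 0. How much of the small changes is dye bias therefore cannot be told. A response common to both tissues, to aluminum or to the transfer and the time of day, may underlie the larger ones. Aluminum, transfer and time of day are confounded in this design.

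In shoot 3 h, root 3 h and root 6 h, replicates 1 and 4 resembled each other, as did replicates 2 and 3, a pattern narrowed to these groups after shoot 6 h was seen. In shoot 6 h replicates 2 and 3 correlated at 0.62 and replicate 1 was closest to replicate 4 (0.32), but replicate 4 was closer to replicates 2 and 3 (mean 0.45). Replicate 4 was scanned in the same calendar year as replicates 2 and 3. Its log ratios correlated at a mean of 0.68 with replicate 1 and 0.26 with replicates 2 and 3 in the 3 groups. A shared scan year alone thus does not account for the likeness of replicates 1 and 4 there, which leaves out shoot 6 h. These values restate the pattern in groups chosen for it and are no separate test. A batch of scanning or hybridisation within a year stays open. Differences between the untreated 0 h samples cannot be told apart from differences between the treated ones. A first test, the mean correlation of deviations of replicates 1 and 4, gave 0.10 in Cy3 and 0.13 in Cy5 and separated nothing, and in a second the Cy3 signals carried a mean share of 0.51 of the covariance, from -0.04 in shoot 3 h to 0.86 in root 3 h. The Cy5 signals carried a larger share in each group (0.71, 1.18 and 1.67, mean 1.19), offset by cross terms down to -1.38, so the shares do not separate the channels. No biological explanation was tested.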

How the results depend on the processing

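The runs without the shoot 6 h array of replicate 1 and those of the response averages and overlaps were added after seeing the data. No count below says which probes were called. Unless a reason is named, the cause of a change was not tested. Median centring in place of loess called 12408 probes in shoot 3 h, 10883 in shoot 6 h, 11781 in root 6 h, 4658 in root minus shoot at 3 h, 2146 at 6 h (894 higher and 1252 lower, against 439 and 305) and 5 in root 6 h minus 3 h. Probes rising or falling in both tissues then numbered 3693 and 1785 at 3 h and 3128 and 2094 at 6 h. It turned the averages of root-falling probes in shoots to 0.08 and 0.04. The fit to the compared arrays alone has fewer arrays to estimate the spread and takes none of it from the other groups. Which of the 2 lowered the counts was not tested. It called 152 in shoot 6 h, 1748 in root 3 h, 32 in root 6 h and 20 in root minus shoot at 6 h. The replicate block called 11576 in shoot 3 h, 8935 in shoot 6 h, 8587 in root 6 h, 12 in root 6 h minus 3 h, 6011 in root minus shoot at 3 h and 2271 at 6 h, and changed no other count by over 1.5 times. The slide as a random block (correlation 0.37) called 80, 6741 and 2893 in the last 3 of these.

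Requiring a 2-fold change, a stricter rule by construction, left 637, 360, 1445 and 626 probes in shoot 3 h, shoot 6 h, root 3 h and root 6 h, 755 and 229 in root minus shoot at 3 and 6 h, and 15396 between the untreated tissues. Scale normalization called 6277 in root 6 h. Root 6 h minus 3 h gave 5 without background subtraction, 4 with Agilent's log ratios or the series table (the same values), 6 with the strict filter on dim probes and 5 with the variance trend. Agilent's log ratios and the series table gave 1992 shoot probes at 24 h. Leaving out a replicate gave 3132 to 5302 probes in shoot 3 h, 1244 to 7211 in shoot 6 h, 5175 to 6749 in root 3 h, 982 to 2701 in root 6 h, 0 to 2 in root 6 h minus 3 h, 788 to 1877 in root minus shoot at 3 h and 6 to 1985 at 6 h. Leaving out the shoot 6 h array of replicate 1 alone gave 2438 in the last. The lowest counts came without replicate 3 or 4 in shoots and replicate 2 or 3 in roots. Shoot 6 h minus 3 h stayed at 0 calls in the alternatives run. The largest shift of the median over all probes was 0.34, between the untreated tissues. No named probe changed sign in any alternative run. The rule that all 4 replicates agree all but fixes the sign in runs that kept the same ratios. Only runs with another background correction or normalization could well have turned it. Of 24 named values, 14 missed the threshold with the compared arrays alone, and 8, 8, 14 and 8 without replicate 1, 2, 3 and 4. None (0) did with the replicate block. The alternatives for gene lists were not run, since 0 probes matched a list. Probes near background, 3099 left out of the test, limit what can be said of weakly expressed transcripts.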

Other observations

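Transcripts biased to one tissue before treatment were followed on arrays that played no part in choosing them. Between 4388 and 4480 probes were at least 4-fold higher in untreated shoots, and in roots they averaged -0.25 ± 0.23 at 3 h and -0.17 ± 0.17 at 6 h (n = 4), against -0.03 ± 0.04 and -0.05 ± 0.08 in shoots. Between 2741 and 2958 probes were at least 4-fold higher in untreated roots, and they averaged 0.14 ± 0.16 and 0.17 ± 0.08 in roots and 0.11 ± 0.19 and 0.18 ± 0.30 in shoots. The root averages of the shoot-biased probes ran from -0.43 to 0.07 at 3 h, where their direction did not hold in every replicate, and from -0.36 to -0.02 at 6 h. At 3 h they were -0.43 and -0.37 in replicates 2 and 3, where the named root falls were largest. In replicates 1 and 4 they were -0.26 and 0.07. The cause of this likeness was not tested.

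For 5737 clones 2 probes were tested. Their changes correlated across clones at 0.99 in shoot 3 h, 0.98 in shoot 6 h, 0.99 in root 3 h and 0.99 in root 6 h. Where both probes of a clone were called, they agreed in direction in 1034 of 1034 clones in shoot 3 h and 1315 of 1316 in root 3 h. The 2 probes were read on the same arrays and can overlap in sequence. Those of Hv2011N24, Hv1056P15 and Hv1119C16 share at least 18 bases. The agreement is thus no independent support for the calls.

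Other splits of the samples were counted for each comparison. For root minus shoot, 1 of 35 splits, the real one, gave as many calls: 2464 at 3 h with 8 as the highest other, 744 at 6 h with 0, and 28544 between the untreated tissues with 0. Same-numbered arrays resembled each other, so the comparable splits are those that part all pairs, and these 8 are too few for a share under 0.05. The highest other among them was 0 in each of these comparisons. For the ratios against 0 h, the 8 sign flips of 4 arrays are too few for a share under 0.05. The real arrays gave the most calls in 1 of 8: 7099 with 0 as the highest other in shoot 3 h, 4816 with 2807 in shoot 6 h, 8905 with 6 in root 3 h and 4002 with 6 in root 6 h. The 2807 came from turning the sign of replicate 1 of shoot 6 h alone. For 6 h minus 3 h the comparison with other splits says nothing about chance, since with 0 calls observed 35 of 35 splits had to give at least as many. The highest other, 1893 in shoots and 4664 in roots, set replicates 1 and 4 against replicates 2 and 3, which points to a structure of the samples.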
